A study of Arabidopsis thaliana with 20 samples.

How the data were processed

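RNA-seq and Ribo-seq were measured in leaves of Arabidopsis WT and rps2 plants that carry 35S:uORFsTBF1-LUC, 8 h after mock treatment or inoculation with Pseudomonas syringae pv. maculicola ES4326 carrying AvrRpt2. Per the labels, 1 lysate was divided for both assays, but the labels do not state that equal replicate numbers mark 1 lysate. The authors deposited gene values in RPKM, 1 table of 12 WT libraries and 1 of 8 rps2 libraries, each with the same 27144 nuclear genes. Per the labels, the authors used CASAVA 1.8.2, Bowtie2 2.0 and HTSeq with TAIR10. The HTSeq version, the counted feature, the strand setting and the reads behind the denominator are not given in the sources used here. How reads shared by close paralogs (IGMT genes, CYP71A12 and CYP71A13, LHCB and RBCS genes) were assigned is not given either. Both tables held 0 chloroplast or mitochondrial genes, so the planned share of organelle reads could not be computed. Positions are not given because the annotation at hand differs in version from the build used for mapping.

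Symbols came from a gene reference that matched 26719 of the 27144 genes and gave a symbol for 10404; RPS2 and other shared symbols were set by identifier. Because RPKM values of a library fall on steps of 1 read, whole reads could be recovered: within a tolerance of 0.02 reads, 100% of the values above 0 of 22740 genes fitted, and in simulated data 99.95% of 7995 genes were recovered. The totals of these reads, given per group with the data, are the depth. They include only reads assigned to genes, and the spread between replicates exceeded counting error, with a chi-square per degree of freedom of 1.86 to 19.7.

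Libraries were grouped by background, treatment and assay into 8 groups. Values were analysed as log2(RPKM + 1), keeping genes with a mean RPKM of at least 1 over the libraries of each fit, with limma 3.58.1 in R 4.3.3 (trended empirical Bayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes tested). Translational efficiency was the Ribo-seq minus the RNA-seq change in 1 fit of both assays. Differences between backgrounds were interaction terms of changes taken within each table. In all, 9 comparisons were made: RNA-seq, Ribo-seq and translational efficiency, each in WT, in rps2 and as WT minus rps2. Background and table cannot be told apart.

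For 25 gene lists with 408 genes, fixed before the data were examined, camera from limma compared each list with all other genes at a preset correlation of 0.01, two-sided and adjusted over 25 lists, and again with a correlation estimated from the data. The second form tests on the residual degrees of freedom of a fit, 4 in each WT assay and 2 in each rps2 assay. It thus has little power, and a call lost there does not show that a list was unchanged. They were aromatic amino acid biosynthesis, phenylpropanoid, camalexin, indole and aliphatic glucosinolate, sphingolipid, salicylic acid, N-hydroxypipecolic acid, intracellular and cell-surface receptors, WRKY factors, jasmonate synthesis and response, ethylene, cell death, light harvesting, carbon fixation, ribosomal proteins, translation factors, endoplasmic reticulum folding, chaperones, cell expansion, and guard cell, phloem and epidermis markers. Named genes were chosen by a fixed rule: among called genes whose groups did not overlap, the 8 largest rises and 8 largest falls with a symbol; from each list up to 4 members with the largest change in WT RNA-seq and up to 2 in the comparison at hand; and always RPS2, RIN4, TBF1, PR1, ICS1, WRKY33 and PAD3. For translational efficiency, overlap was judged on Ribo-seq to RNA-seq ratios of libraries with equal replicate numbers, a pairing that the labels do not state.

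Alternatives were a pseudocount of 0.1, no filter, quantile scaling, median-centred libraries, a fit over both assays of a background, replicate number as a block, the estimated list correlation and leaving out each library in turn; where that left 1 library in a group, limma assumed that it varied like the other groups. Chosen after seeing the data were voom on the recovered reads, Ribo-seq values rescaled to the mean RNA-seq total, a pseudocount of 0.1 with the lysate block, a pseudocount of 0.25 with median-centred libraries, leaving out libraries for the lists, and the counts of shared and opposite genes and of list members under the alternatives. The fits were tested on simulated data, with 100 genes each at a 2-fold and a 4-fold change, and efficiency calls on 20 simulations with no change in efficiency. All these simulations drew each gene on its own, with the same spread for genes of similar abundance. They left out spread shared by the genes of a library, so the numbers found and wrongly called may be too favourable for the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Luciferase activity and sequence reads are not analysed here.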

Results

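RNA-seq and Ribo-seq, which sequences the mRNA fragments that ribosomes protect, were measured in leaves of Arabidopsis thaliana carrying 35S:uORFsTBF1-LUC, a luciferase reporter behind the upstream open reading frames of the immune regulator TBF1. Plants were wild type (WT) or rps2, a mutant of the immune receptor RPS2, which recognises the bacterial effector AvrRpt2. Leaves received 10 mM magnesium chloride (mock) or Pseudomonas syringae pv. maculicola ES4326 carrying AvrRpt2 at an optical density of 0.01, and were sampled after 8 h. The 20 libraries formed 8 groups of background, treatment and assay, with 3 libraries per WT group and 2 per rps2 group. Reads assigned to genes numbered 14675852 to 26949509 per library for WT RNA-seq, 5054176 to 9274817 for WT Ribo-seq, 8285414 to 21823731 for rps2 RNA-seq and 3885834 to 9468621 for rps2 Ribo-seq. Levels are mean RPKM ± SD over libraries, and log2 changes carry the standard error of the limma fit. The labels do not say whether replicates came from separate pools of plants, so p-values of single genes measure only the spread between these libraries. limma takes much of that spread from a trend over all genes. Its prior degrees of freedom were 21.0 in WT RNA-seq and 57.3 in WT Ribo-seq, against 4 residual. In rps2 they were 55.2 in RNA-seq and unlimited in Ribo-seq, against 2 residual. Very small p-values thus do not show the spread of 1 gene alone. The p-values of camera at the preset correlation compare the genes of a list with all other genes. They do not measure the spread between libraries and can be very small with few of them.

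Within groups, libraries correlated across genes at r = 0.970 to 0.996, genes not being independent replicates. The first principal component held 69.9% of the variance of the RNA-seq libraries and 69.4% of that of the Ribo-seq libraries. RPS2 transcripts were present in the mutant, at 5.09 ± 1.44 RPKM in mock and 7.01 ± 0.244 RPKM in AvrRpt2 libraries (n = 2 each), so the transcript level does not show the genotype. TBF1 (AT4G36990), a heat-shock-factor-like regulator of the switch from growth to defence, rose from 33.4 to 127 RPKM in WT RNA-seq (log2 change 1.89 ± 0.11) and by 1.25 ± 0.15 in WT Ribo-seq (n = 3 per group). In rps2 its RNA-seq change was 0.13 ± 0.22 (adjusted p = 0.914). The reporter carries upstream open reading frames of TBF1, and the counted feature is not given. Reads of the reporter may thus be part of every TBF1 value given here, that of translational efficiency included. PR1, a late marker of salicylic acid signalling, stayed below the level tested, at no more than 0.462 RPKM in every RNA-seq library except rps2 mock replicate 1, at 2.70 RPKM.

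**Figure D1:**
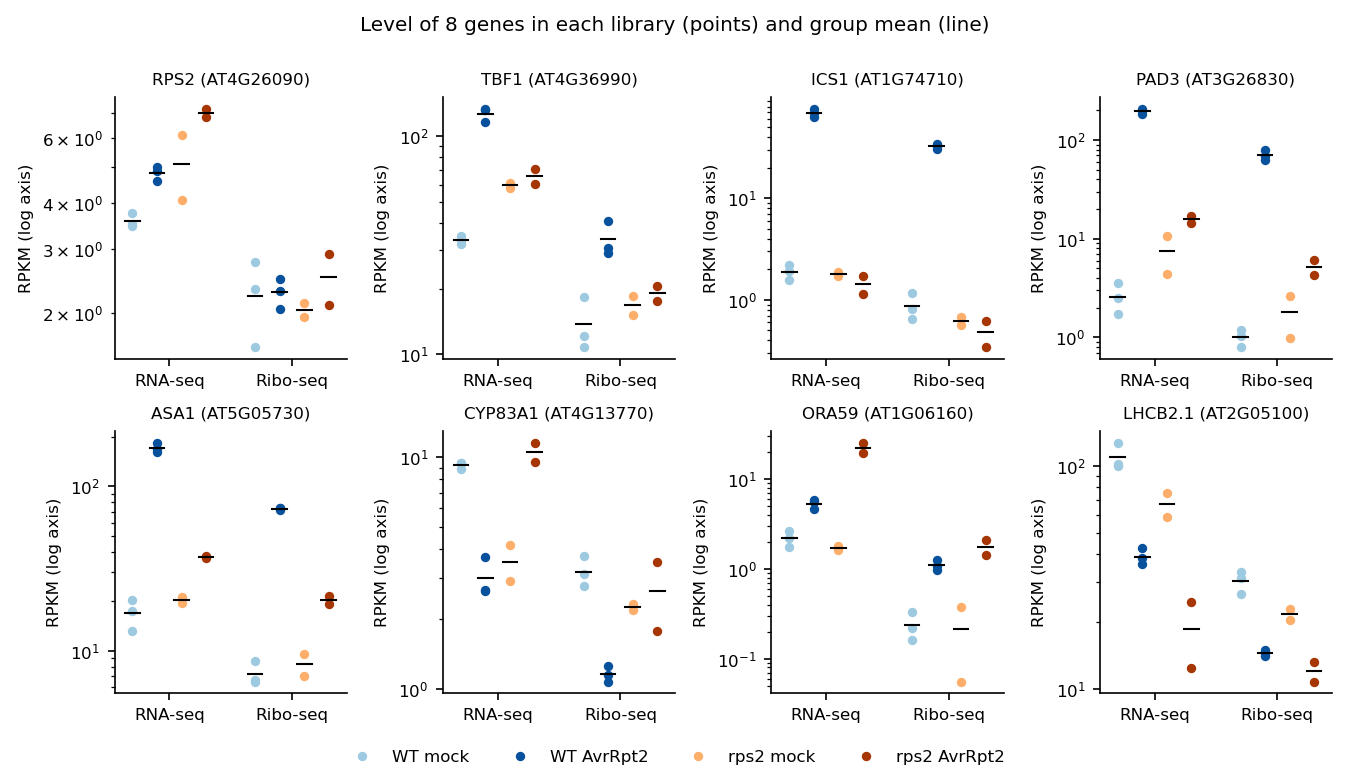
RPKM on a log axis for 8 genes in each mock and AvrRpt2 library of WT and rps2, by RNA-seq and Ribo-seq; points are libraries and lines are group means. ICS1, PAD3 and ASA1 were far higher after AvrRpt2 in WT, whereas ORA59 was highest in rps2 after AvrRpt2.

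The first comparison asked which transcripts change during RPS2-mediated immunity in WT. Genes that make defence compounds were among the largest rises. PAD3, which completes camalexin synthesis, went from 2.58 to 197 ± 10.5 RPKM (log2 change 5.82 ± 0.13, n = 3 per group). CYP79B2, which turns tryptophan into indole-3-acetaldoxime, went from 3.88 ± 0.574 to 236 ± 14.7 RPKM (5.6 ± 0.11, adjusted p = 1.58e-22). Of salicylic acid synthesis, ICS1, the isochorismate synthase, went from 1.90 ± 0.319 to 69.1 ± 6.48 RPKM, and PBS3, which joins isochorismate to glutamate, rose by 5.38 ± 0.11. BAP2, a C2-domain protein that restrains cell death, rose by 5.92 ± 0.12 and AACT1 (AT5G61160), an agmatine coumaroyltransferase, by 5.31 ± 0.12. NHL10, an immune marker, rose by 5.24 ± 0.12 and ABCG40, an abscisic acid importer, by 4.77 ± 0.13. Among the largest falls were EXL5 (exordium-like) at -3.38 ± 0.12, the arabinogalactan protein AGP17 at -3.33 ± 0.12, SHY2, a repressor of auxin response, at -2.49 ± 0.16, BZIP61, a transcription factor, at -2.41 ± 0.16 and ARR6, a cytokinin response regulator, at -2.34 ± 0.11.

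Among lists of metabolic genes fixed before the data were examined, tryptophan-derived defence pathways moved furthest in WT RNA-seq. All 7 measured camalexin genes rose (median log2 change 2.83; CYP71A12 4.56 ± 0.12, CYP71A13 2.83 ± 0.11, close paralogs that act after CYP79B2). Of 14 indole glucosinolate genes 13 rose, among them CYP81F2, which hydroxylates the indole ring, at 4.61 ± 0.11 and the regulator MYB51 at 4.32 ± 0.11, and 1 fell (median 2.58). Of 31 aromatic amino acid genes 20 rose and 2 fell (3 adjusted over the list alone, median 0.62). ASA1, the alpha subunit of anthranilate synthase, rose from 17 ± 3.52 to 171 ± 11.3 RPKM (3.28 ± 0.12), and ADT4, an arogenate dehydratase, by 3.26 ± 0.12. Phenylpropanoid genes rose in 14 of 18 cases and fell in 2 (15 up and 2 down adjusted over the list alone, median 0.78). CCR2 (AT1G80820), a cinnamoyl-CoA reductase, rose by 4.62 ± 0.11 and PAL2, a phenylalanine ammonia-lyase, by 3.00 ± 0.11. These 4 lists were called by camera at adjusted p = 5.57e-08 or below, against an adjusted p = 0.292 with an estimated correlation. Aliphatic glucosinolate genes went the other way, 8 of 10 falling and 1 rising (median -0.79). CYP83A1, which oxidises methionine-derived aldoximes, went from 9.20 ± 0.312 to 3.00 ± 0.595 RPKM (-1.36 ± 0.12). MAM1, which elongates the methionine side chain, changed by -1.19 ± 0.13, whereas the sulfotransferase SOT17 rose by 2.74 ± 0.11. That list's call (adjusted p = 0.0216) ended with median-centred libraries, and its adjusted p = 0.335 with an estimated correlation. Sphingolipid genes split, 7 up and 6 down of 24 (adjusted p = 0.155), with the inositolphosphorylceramide synthase ERH1 at 2.93 ± 0.12 and the ceramide synthase LOH2 at 2.39 ± 0.12.

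Immune signalling lists rose in WT RNA-seq. Of 17 salicylic acid genes 16 rose and none fell, or 1 with quantile scaling or voom (median 1.87; EDS5, which exports isochorismate from the plastid, 4.22 ± 0.12; CBP60G, a regulator of ICS1, 3.86 ± 0.11). Cell-surface receptor and MAP kinase genes rose in 18 of 20 cases and fell in 1 (median 1.14; RBOHD, the oxidative-burst NADPH oxidase, 3.51 ± 0.10; MPK3 2.67 ± 0.11). WRKY factors rose in 12 of 17 cases with none falling (1 down adjusted over the list alone, 2 with quantile scaling and 3 under voom, median 1.09; WRKY46 4.54 ± 0.13; WRKY33, an activator of camalexin genes, 3.35 ± 0.11). Of 16 intracellular receptor genes and partners 12 rose (median 0.66; NDR1, needed for RPS2 function, 1.2 ± 0.13). RPS2 itself rose by 0.35 ± 0.12 (adjusted p = 0.0125) and RIN4, the host protein that RPS2 guards, by 0.62 ± 0.13. Jasmonate synthesis genes rose in 9 of 13 cases and fell in 1 (median 0.58; LOX4, a lipoxygenase, 3.07 ± 0.11). Jasmonate response genes rose in 11 of 16 cases and fell in 2 (median 1.1; TAT3, a tyrosine aminotransferase, 3.69 ± 0.12). Cell death genes rose in 7 of 8 cases (median 1.22; BON1, a copine that restrains cell death, 2.48 ± 0.11), and chaperones in 5 of 6 (median 0.76; HSP90.1 1.41 ± 0.12). N-hydroxypipecolic acid genes rose in 3 of 5 cases (median 0.86; FMO1, which makes that signal, 2.07 ± 0.13). All of these lists were called (adjusted p = 0.0125 or below), with an adjusted p = 0.292 with an estimated correlation. Ethylene genes rose in 6 of 11 cases (median 0.45; ERF6, an ethylene response factor, 3.14 ± 0.12, adjusted p = 0.000497, and adjusted p = 0.335 with an estimated correlation).

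Photosynthesis genes fell in WT RNA-seq, among them 36 of 36 light harvesting and photosystem genes (median -0.65; LHCB2.1, an antenna protein with close paralogs, -1.45 ± 0.11). Carbon fixation genes fell in 17 of 18 cases (18 adjusted over the list alone, median -0.66; PRK, the phosphoribulokinase, -1.21 ± 0.12). Both lists were called (adjusted p = 1.64e-07 and 6.67e-05), with an adjusted p = 0.457 with an estimated correlation. Cell expansion genes fell in 6 of 7 cases (median -0.92; XTH9, a wall-modifying enzyme, -1.77 ± 0.16, adjusted p = 0.0083, and adjusted p = 0.335 with an estimated correlation). Cytosolic ribosomal protein genes were not called (9 of 30 lower, 7 adjusted over the list alone, none higher, median -0.21; 13 lower with median-centred libraries, 28 with quantile scaling, median -0.41, and 28 under voom, median -0.31; adjusted p = 0.0666, and 0.03 with median-centred libraries). Translation factors were not called (1 of 12 lower, 6 with quantile scaling and 5 under voom, adjusted p = 0.814). Nor were endoplasmic reticulum folding genes (5 higher and 5 lower of 18, 4 lower adjusted over the list alone, median -0.10 and mean 0.03, adjusted p = 0.818), although BZIP60, an unfolded-protein-response regulator, rose by 1.72 ± 0.10. The cell-type lists were not called: guard cell markers (1 of 7 lower, none adjusted over the list alone, adjusted p = 0.945), phloem markers (3 of 7 lower, 5 with quantile scaling or voom, adjusted p = 0.403) and epidermis markers (4 of 5 lower, adjusted p = 0.131).

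**Figure D2:**
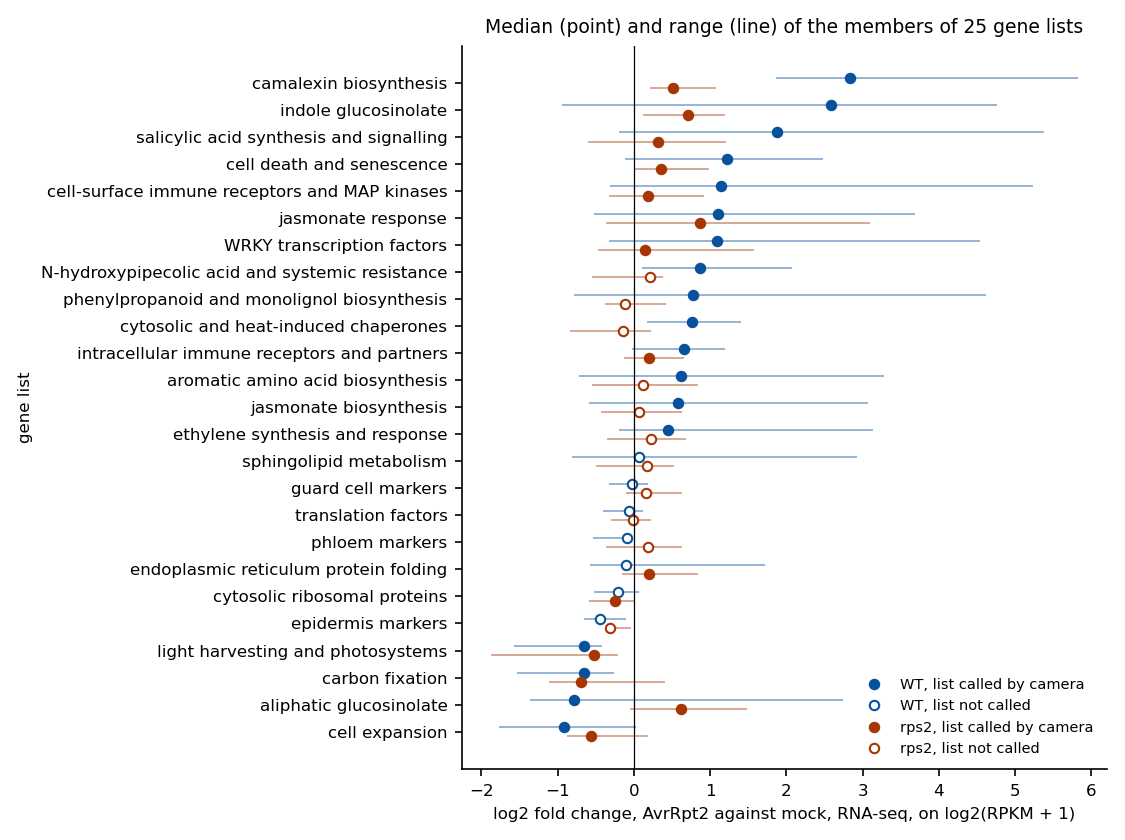
Median (point) and range (line) of the log2 changes of the measured members of each of the 25 gene lists in WT and rps2 RNA-seq, on a log2 axis; filled points were called by camera with its preset correlation, 18 lists in WT and 14 in rps2. With an estimated correlation none of those calls held, but that test has little power, with 4 residual degrees of freedom in WT and 2 in rps2.

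In all, 8394 of 14641 genes tested in WT RNA-seq passed the limma test, 3180 up and 5214 down, of which 1246 rose and 490 fell at least 2-fold. Over all genes tested, the AvrRpt2 and mock libraries did not overlap in 9327 (63.7%), where 10% would by chance. The median over all genes tested was -0.13. Voom, which changes scaling, pseudocount and weights together, shifted it by -0.12 and called 3008 up and 7028 down, against 3440 and 5677 with median-centred libraries and 3424 and 5835 with quantile scaling.

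Ribo-seq in WT asked which transcripts change in ribosome occupancy, and largely the same pathways moved. CYP79B2 rose by 5.23 ± 0.14 and PAD3 by 5.15 ± 0.14, ICS1 went from 0.879 to 32.5 RPKM, and ASA1 from 7.27 to 73.2 RPKM (n = 3 per group). CYP81F2 rose by 4.51 ± 0.14, NHL10 by 4.99 ± 0.14, PBS3 by 4.81 ± 0.14 and BAP2 by 4.70 ± 0.15. The largest falls were AGP17 at -2.73 ± 0.14, EXL5 at -2.55 ± 0.15, the ABC transporter ABCG22 at -2.05 ± 0.14 and PKS2, a phytochrome kinase substrate, at -1.90 ± 0.15, among genes with a symbol. All 7 camalexin genes (median 2.45) and all 13 measured indole glucosinolate genes (median 2.70) rose. Of 27 aromatic amino acid genes 19 rose and 2 fell (ADT4 3.17 ± 0.14), of 17 phenylpropanoid genes 15 rose and 1 fell (CCR2 4.14 ± 0.14), and of 15 salicylic acid genes 13 rose (median 1.60). Camalexin was called at adjusted p = 2.77e-15 and 0.0267 with an estimated correlation. The other 4 lists were called at adjusted p = 8.76e-10 or below, with an adjusted p = 0.159 or 0.29 with an estimated correlation.

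Immune and photosynthesis lists followed in WT Ribo-seq. Cell-surface receptor and MAP kinase genes rose in 16 of 20 cases (17 up and 1 down adjusted over the list alone; RBOHD 3.32 ± 0.14) and WRKY factors in 10 of 15 (WRKY33 3.05 ± 0.14). Jasmonate response genes rose in 8 of 13 cases and fell in 1 (TAT3 3.13 ± 0.15), ethylene genes rose in 6 of 10 and fell in 1, and cell death genes rose in 6 of 7 (BON1 2.2 ± 0.14). Light harvesting genes fell in 35 of 36 cases (median -0.60) and carbon fixation genes in 17 of 18 (median -0.65; PRK -1.13 ± 0.13). Each of these 7 lists was called (adjusted p = 0.000378 or below), with an adjusted p = 0.29 with an estimated correlation. A weaker call was made for N-hydroxypipecolic acid genes (4 of 4 up, adjusted p = 0.0383, and adjusted p = 0.304 with an estimated correlation). Intracellular receptors (9 of 15 up, adjusted p = 0.0126) and ribosomal proteins (8 of 29 down; 3 without mock replicate 1, 5 without AvrRpt2 replicate 1 and 4 without AvrRpt2 replicate 2; 21 with quantile scaling, median -0.44, and 20 under voom, median -0.36, against -0.20; adjusted p = 0.0382) were called, both with an adjusted p = 0.482 with an estimated correlation. Jasmonate synthesis (7 up and 1 down of 13, adjusted p = 0.00475) and cell expansion (4 of 6 down, 5 adjusted over the list alone, adjusted p = 0.0382, and 0.14 with median-centred libraries) had an adjusted p = 0.415 with an estimated correlation. Chaperones rose in 3 of 3 cases (adjusted p = 0.0382, and adjusted p = 0.29 with an estimated correlation). The aliphatic glucosinolate (1 up and 4 down of 5, adjusted p = 0.337), sphingolipid (7 up and 3 down of 21, 8 up adjusted over the list alone, adjusted p = 0.172), translation factor, folding, guard cell, phloem and epidermis lists were not called.

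In WT Ribo-seq limma called 4785 of 11144 genes, 2162 up and 2623 down. Over all genes tested, the groups did not overlap in 5622 (50.4%), where 10% would by chance. Under voom, which shifted the median of all genes by -0.18, 2021 rose and 4731 fell. The balance turned without WT mock replicate 3, to 2545 up and 2028 down, and without AvrRpt2 replicate 3, to 1973 and 1869.

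**Figure D3:**
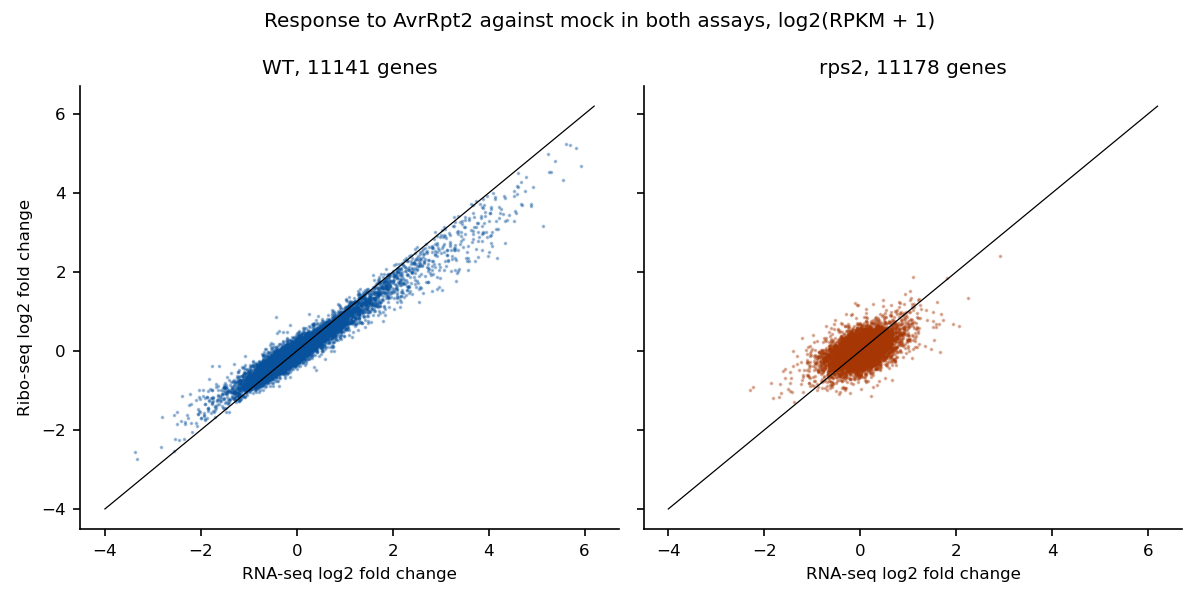
Log2 change in Ribo-seq (vertical axis) against log2 change in RNA-seq (horizontal axis) for each gene measured by both, 11141 in WT and 11178 in rps2; the line marks equality. WT genes follow the line with a slope of 0.81, rps2 genes scatter more widely with a slope of 0.43.

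Changes in RNA-seq and Ribo-seq ran together in WT across genes (Pearson r = 0.97, Spearman rho = 0.94, genes not being independent replicates). Of the genes tested by both assays 2080 were called up in both, against 531.3 by chance, 2495 down in both, against 891.8, and 5 in opposite directions. These were SDH7 (AT5G62575), CLE41, AT5G58005, AT3G56020 and AT5G24980, named after their values were seen except SDH7. The slope of Ribo-seq on RNA-seq was 0.81 with a pseudocount of 1, 0.93 with 0.1 and 0.96 under voom.

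Translational efficiency, the Ribo-seq change minus the RNA-seq change, asked which mRNAs gained or lost ribosomes beyond their change in abundance in WT. Lower values were estimated for genes whose transcripts rose, such as CYP71A12 at -1.06 ± 0.19, WRKY75 at -1.12 ± 0.19 and MYB122, a regulator of indole glucosinolate genes, at -1.31 ± 0.19 (n = 3 per group and assay). The lowest among genes with a symbol were TDR1, an ethylene response factor, at -1.62 ± 0.19 and the methyltransferase PXMT1 at -1.59 ± 0.18. Higher values were estimated for GER3, a germin-like protein, at 1.38 ± 0.32 and SHY2 at 0.94, whose transcripts fell. None of these 7 genes was called under voom or with a pseudocount of 0.1, and CYP71A12 turned to 0.26 with rescaled Ribo-seq values and WRKY75 to 0.10 under voom. GER3 also lost its call without WT mock RNA-seq replicate 1 or 2 or WT mock Ribo-seq replicate 3, and SHY2 without WT mock RNA-seq replicate 2, WT AvrRpt2 RNA-seq replicate 1 or WT mock Ribo-seq replicate 1. TBF1 was at -0.64 ± 0.20 (adjusted p = 0.0875), PAD3 at -0.67 ± 0.19 (adjusted p = 0.0625) and ASA1 at -0.10 ± 0.18, none of them past the test. Camalexin genes (1 of 7 down, 3 adjusted over the list alone, median -0.40, adjusted p = 2.3e-05) and salicylic acid genes (1 of 15 down, 8 adjusted over the list alone, median -0.43, adjusted p = 4.63e-09) were called lower, both with an adjusted p = 0.24 with an estimated correlation. So were WRKY factors (2 of 15 down, 3 adjusted over the list alone, adjusted p = 0.000347) and indole glucosinolate genes (2 of 13 down, adjusted p = 0.00274), both with an adjusted p = 0.81 with an estimated correlation. Cell expansion genes (1 of 6 up, median 0.29, adjusted p = 0.00215) were called higher, with an adjusted p = 0.485 with an estimated correlation. So were light harvesting genes (median 0.11, and -0.03 with quantile scaling, adjusted p = 0.00274), with an adjusted p = 0.855 with an estimated correlation. Under voom the medians of the camalexin, salicylic acid and indole glucosinolate lists were -0.01, -0.13 and 0, against -0.40, -0.43 and -0.11. Intracellular receptors, cell-surface receptors and jasmonate synthesis genes were called lower at adjusted p = 0.0331, with an adjusted p = 0.81 to 0.855 with an estimated correlation.

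limma called 202 of 11141 genes for efficiency in WT, 42 up and 160 down. Without WT mock RNA-seq replicate 2 it called 111 (20 and 91). The genes called up were 17 without WT mock RNA-seq replicate 1, 26 without WT AvrRpt2 RNA-seq replicate 1 and 71 without WT AvrRpt2 RNA-seq replicate 2. The number of lists called, 9, was 5 without WT AvrRpt2 RNA-seq replicate 1, WT mock Ribo-seq replicate 3 or WT AvrRpt2 Ribo-seq replicate 3. The calls ended with a pseudocount of 0.1 (0 by limma, 263 at unadjusted p under 0.05), with Ribo-seq RPKM rescaled to the mean RNA-seq total (0 and 228) and under voom (0 and 489), where 557 would pass unadjusted by chance. Data simulated with no change in efficiency gave between 151 and 202 calls with a pseudocount of 1, where the data gave 202. The test could make such calls: of 100 simulated genes, 74 with a 2-fold and 91 with a 4-fold change in efficiency were found. It also called 5 unchanged genes.

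**Figure D4:**
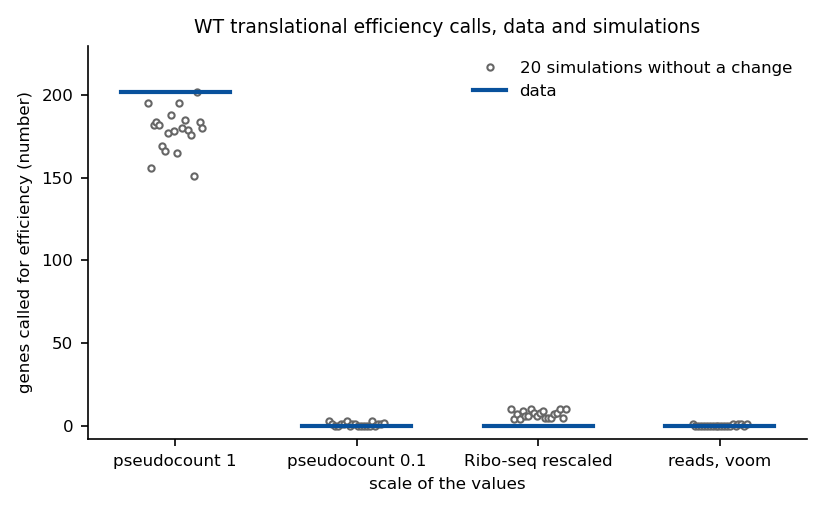
Number of genes called for a change in WT translational efficiency in the data and in 20 simulations with no such change, under a pseudocount of 1, a pseudocount of 0.1, rescaled Ribo-seq values and voom. With a pseudocount of 1 the data gave 202 calls and the simulations 151 to 202; in the other settings the data gave 0.

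Without a functional RPS2, the question was which transcripts still respond to the AvrRpt2 strain. Jasmonate response genes rose. ORA59, the ethylene response factor that joins both pathways, went from 1.72 ± 0.141 to 22.4 ± 3.85 RPKM (log2 change 3.10 ± 0.24, adjusted p = 1.42e-14, n = 2 per group). JAZ8, a jasmonate repressor, rose by 2.05 ± 0.25, PR4, a chitin-binding defence protein, by 1.81 ± 0.22 and AACT1 by 2.26 ± 0.25. Of the aliphatic glucosinolate genes, CYP83A1 rose from 3.53 ± 0.884 to 10.5 ± 1.37 RPKM (1.35 ± 0.25), MAM1 from 4.63 to 12.2 RPKM, and BCAT4, the aminotransferase that starts methionine chain elongation, from 1.60 to 6.16 RPKM. The antenna gene LHCB2.1 fell from 67.0 to 18.5 RPKM (-1.87 ± 0.23) and LHCB1.2 fell by 1.66 on the log2 scale. GI, a clock and flowering regulator, fell from 7.07 to 1.3 RPKM, and the kinase CIPK20 changed by -2.24. Each of these genes kept its call whichever library was left out. With quantile scaling or median-centred libraries, of these genes ORA59, JAZ8 and GI were still called, and with no filter on low values only ORA59.

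By list, 10 of 15 jasmonate response genes rose in rps2 RNA-seq (12 adjusted over the list alone, median 0.87, adjusted p = 2.56e-21). So did 4 of 10 aliphatic (5 adjusted over the list alone, median 0.62, adjusted p = 3.51e-08) and 5 of 13 indole glucosinolate genes (10 adjusted over the list alone, median 0.71, adjusted p = 5.43e-11), and 2 of 7 camalexin genes, PAD3 and CYP79B2 (4 adjusted over the list alone, median 0.51, adjusted p = 2.68e-05). Each of these 4 lists had an adjusted p = 0.445 with an estimated correlation. PAD3 (1.08 ± 0.25) lost its call without mock replicate 1 or AvrRpt2 replicate 1, and CYP79B2 (1.06 ± 0.25) without mock replicate 2, AvrRpt2 replicate 1 or AvrRpt2 replicate 2. Light harvesting genes fell in 6 of 36 cases (12 adjusted over the list alone, median -0.53, adjusted p = 1.06e-21) and carbon fixation genes in 6 of 18 (13 adjusted over the list alone, median -0.69, adjusted p = 1.65e-13). Both lists had an adjusted p = 0.539 with an estimated correlation. Ribosomal proteins were called lower as a list with no gene passing (median -0.25, adjusted p = 2.78e-06, and adjusted p = 0.539 with an estimated correlation). Cell expansion genes fell in 1 of 7 cases (4 adjusted over the list alone, adjusted p = 0.000494, and adjusted p = 0.445 with an estimated correlation). Weaker rises were called for salicylic acid (2 of 18, 3 adjusted over the list alone, adjusted p = 0.00577) and cell death genes (1 of 8, adjusted p = 0.00638), both with an adjusted p = 0.539 with an estimated correlation. WRKY factors (3 of 16; WRKY75 1.58 ± 0.25), cell-surface receptors (1 of 19, 3 adjusted over the list alone), folding genes (1 of 18) and intracellular receptors (median 0.20) were called higher at adjusted p = 0.0113 to 0.0272. They had an adjusted p = 0.657 with an estimated correlation. ICS1 was at 1.8 ± 0.101 RPKM in mock and 1.42 ± 0.405 RPKM in AvrRpt2 libraries (adjusted p = 0.876). Aromatic amino acid (1 of 31 up, adjusted p = 0.0956), phenylpropanoid (adjusted p = 0.192) and ethylene genes (0 of 11 by limma and 1 up by voom, 1 adjusted over the list alone, median 0.22, adjusted p = 0.189) were not called as lists.

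The numbers of members called in rps2 RNA-seq moved with the scaling and with single libraries. With quantile scaling or median-centred libraries 3 jasmonate response genes and no member of any other list were called. The prior degrees of freedom of limma also fell there, from 55.2 to 5.07 and 5.25, so lost calls do not show lost changes. Voom called 10 jasmonate response, 6 indole and 3 aliphatic glucosinolate, 2 WRKY, 1 camalexin, 6 light harvesting and 9 carbon fixation genes. Without mock replicate 2, AvrRpt2 replicate 1 and AvrRpt2 replicate 2 in turn, jasmonate response genes called were 3, 5 and 8 (10 with all libraries), indole glucosinolate genes 1, 3 and 2 (5), WRKY factors 1 each (3), light harvesting genes 3, 3 and 28 (6) and carbon fixation genes 1, 1 and 12 (6). Without mock replicate 1 they were 9, 5, 4, 4 and 3. The 2 salicylic acid genes, PR2 and PR5, both lost their calls without mock replicate 2 or AvrRpt2 replicate 1, PR5 also without mock replicate 1 or AvrRpt2 replicate 2. Without mock replicate 2 or AvrRpt2 replicate 1, NAC6 of the cell death, MPK3 of the cell-surface and CRT3 of the folding list lost their calls, CRT3 also without AvrRpt2 replicate 2. EXPA11 of the cell expansion list lost its call without mock replicate 1 or 2 or AvrRpt2 replicate 2, and ASA1 of the aromatic list lost it in each of the 4 fits.

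limma called 369 of 14912 genes in rps2 RNA-seq, 212 up and 157 down, 109 and 81 of them at least 2-fold. The count rested on single libraries and on the settings. It was 778 without mock replicate 1 (588 up and 190 down), 99 without mock replicate 2 (46 and 53), 154 without AvrRpt2 replicate 1 (107 and 47) and 353 without AvrRpt2 replicate 2 (132 and 221). It was 14 with quantile scaling, 16 with median-centred libraries and 2 with no filter. At unadjusted p under 0.05 limma gave 1726 genes as deposited, 2156 with quantile scaling, 2143 with median-centred libraries and 1678 with no filter. The prior degrees of freedom of limma were 55.2, 5.07, 5.25 and 4.62 in that order. The fewer adjusted calls thus do not show that the changes were absent. Of 100 simulated genes with a 2-fold change the test found 64, and of 100 with a 4-fold change 93. It also called 35 unchanged genes, against 8 by voom. The simulated reads held no spread shared by the genes of a library, so they do not show how far calls rest on 1 library.

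In rps2 Ribo-seq, which asked the same of ribosome occupancy, KTI1, a Kunitz protease inhibitor, rose by 1.88 ± 0.26 and PR4 by 1.85 ± 0.26 (n = 2 per group). Both kept their calls in every setting except that with no filter on low values, in which limma called 0 genes (1011 at unadjusted p under 0.05). Voom was run on the filtered genes alone and called 417. The lipase PLA2A rose by 1.51 ± 0.25, AACT1 by 1.34 ± 0.25 and ASA1 from 8.31 to 20.4 RPKM (1.21 ± 0.26). The largest falls among genes with a symbol were the flowering repressors CDF3 at -1.29 ± 0.26 and CDF1 (AT5G62430) at -1.05 ± 0.24, with GI at -1.18 ± 0.25. The calls of these 6 genes ended without mock replicate 2, that of ASA1 also without AvrRpt2 replicate 2, that of GI without mock replicate 1, and those of CDF3 and CDF1 also without mock replicate 1 or AvrRpt2 replicate 2. Jasmonate response genes rose in 2 of 13 cases (11 adjusted over the list alone, median 0.61, adjusted p = 1.4e-12) and aromatic amino acid genes in 4 of 28 (6 adjusted over the list alone, median 0.34, adjusted p = 9.85e-09). The 2 jasmonate response genes, JAZ7 and TAT3, lost their calls whichever library was left out. The 4 aromatic ones lost theirs without mock replicate 2 or AvrRpt2 replicate 2, and 3 of them without mock replicate 1 or AvrRpt2 replicate 1. Camalexin genes rose in 1 of 5 cases, PAD3 (4 adjusted over the list alone, adjusted p = 8.59e-08), a call that ended without mock replicate 2 or AvrRpt2 replicate 1. Indole glucosinolate genes had no member called over all genes (7 of 11 adjusted over the list alone, median 0.58, adjusted p = 1.26e-09), nor had phenylpropanoid (adjusted p = 0.0134) and jasmonate synthesis genes (adjusted p = 0.00633). Light harvesting (2 of 36 down adjusted over the list alone, median -0.24, adjusted p = 3.7e-09) and carbon fixation genes (median -0.20, adjusted p = 0.000664) were called lower as lists. Each of these 8 lists had an adjusted p = 0.915 with an estimated correlation, and 13 lists were called without AvrRpt2 replicate 2. Salicylic acid, WRKY and intracellular receptor genes were not called as lists (adjusted p = 0.109 to 0.386). Voom called more members: 8 of 13 jasmonate response, 9 of 28 aromatic amino acid, 4 of 5 camalexin, 8 of 11 indole glucosinolate, 1 of 15 phenylpropanoid and 4 of 13 jasmonate synthesis genes up, and 9 of 36 light harvesting and 5 of 18 carbon fixation genes down.

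limma called 86 of 11180 genes in rps2 Ribo-seq, 58 up and 28 down. The count was 23 without mock replicate 1, 3 without mock replicate 2, 195 without AvrRpt2 replicate 1 (51 up and 144 down) and 29 without AvrRpt2 replicate 2, and 46 with median-centred libraries. Across genes, RNA-seq and Ribo-seq changes in rps2 correlated at r = 0.52, with 33 genes called up in both, against 0.9 by chance, and 13 down in both, against 0.3. Under voom these were 83 and 46, with median-centred libraries 1 and 5 and with quantile scaling 1 and 4. Leaving out 1 library gave between 3, without mock Ribo-seq replicate 2, and 30 up in both, and at most 17 down in both, without AvrRpt2 Ribo-seq replicate 1.

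No gene passed the test of translational efficiency in rps2: limma called 0 of 11178 genes, 320 passed at unadjusted p under 0.05 where 559 would by chance. Voom called 0 (453 unadjusted). One library decided several of the values: limma called 28 genes without mock RNA-seq replicate 1, 59 without AvrRpt2 Ribo-seq replicate 1, and 1 without mock RNA-seq replicate 2, AvrRpt2 RNA-seq replicate 2, mock Ribo-seq replicate 2 or AvrRpt2 Ribo-seq replicate 2. Across genes the rps2 efficiency change ran against the RNA-seq change, at a Spearman rho of -0.60, and of -0.49 under voom. Since the RNA-seq change enters efficiency with a minus sign, the list calls here were not separated from spread in RNA-seq. Aliphatic glucosinolate genes were called lower as a list (median -1.07, 3 of 5 down adjusted over the list alone, adjusted p = 8.88e-08, and adjusted p = 0.579 with an estimated correlation). BCAT4 was at -1.42 ± 0.34, CYP83A1 at -1.23 ± 0.35 and MAM1 at -1.07 ± 0.35, none of them past the test over all genes. Jasmonate response (median -0.30, adjusted p = 0.00187), folding (median -0.17, adjusted p = 0.0447) and phloem genes (median -0.28, adjusted p = 0.0472) were called lower. Light harvesting (median 0.33), carbon fixation (0.45), ribosomal protein (0.29), aromatic amino acid (0.30) and phenylpropanoid genes (0.39) were called higher. All 8 of these lists had an adjusted p = 0.841 with an estimated correlation. Cell expansion genes were called higher (median 0.29, adjusted p = 0.00586, and adjusted p = 0.579 with an estimated correlation). Camalexin genes had a median of 0.12 and a mean of -0.02, and ethylene genes a median of -0.03 and a mean of 0.05, neither called. The test found 10 of 100 simulated genes with a 2-fold change in efficiency and 86 of 100 with a 4-fold change. It also called 12 unchanged genes.

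The difference between the WT and rps2 responses asked which transcript changes depend on RPS2. Throughout, a response is called larger (or more) in WT where WT minus rps2 is above 0, and smaller (or less) where it is below 0. A gene that fell further in WT thus counts as smaller, such as EXL5 (-3.38 in WT RNA-seq, difference -3.03). Salicylic acid, camalexin and tryptophan genes responded more in WT. On the log2 scale ICS1 differed by 4.82 ± 0.22 (adjusted p = 5.81e-10), PBS3 by 4.99 ± 0.21, PAD3 by 4.74 ± 0.35, CYP79B2 by 4.54 ± 0.19 and ASA1 by 2.44 ± 0.21 (n = 3 WT and 2 rps2 libraries per treatment). BAP2 led with 5.95 ± 0.34, followed among transporters and defence genes by ABCG40 at 4.83 ± 0.26 and NHL10 at 4.77 ± 0.35. TBF1 differed by 1.76 ± 0.18. The 4 aliphatic glucosinolate genes CYP83A1, MAM1, IPMI2 and BCAT4 fell in WT and rose in rps2. Their rps2 calls ended with quantile scaling, median-centred libraries or no filter, that of IPMI2 also under voom or without rps2 mock RNA-seq replicate 2. The WT fall of BCAT4 was not called without WT mock RNA-seq replicate 2 or with no filter. CYP83A1 differed by -2.71 ± 0.23 (adjusted p = 2.21e-07), MAM1 by -2.43 ± 0.23, IPMI2, an isopropylmalate isomerase subunit, by -2.14 ± 0.32 and BCAT4 by -2.13 ± 0.35. DREB26, a transcription factor of the ethylene response factor family, fell from 66.1 to 17.8 RPKM in WT and rose from 25.6 to 50.0 RPKM in rps2 (difference -2.75 ± 0.25, adjusted p = 4.96e-07). Its opposite calls ended without rps2 mock RNA-seq replicate 2 or rps2 AvrRpt2 RNA-seq replicate 2, and with quantile scaling, median-centred libraries or no filter. Mock levels of DREB26 and CYP83A1 were lower in rps2 than in WT, in separate tables. After AvrRpt2 both genes in rps2 lay nearer their WT mock level, so their opposite responses started from different levels. RPS2 and RIN4 themselves differed by -0.07 ± 0.22 and 0.57 ± 0.23 (adjusted p = 0.862 and 0.0911).

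**Figure D5:**
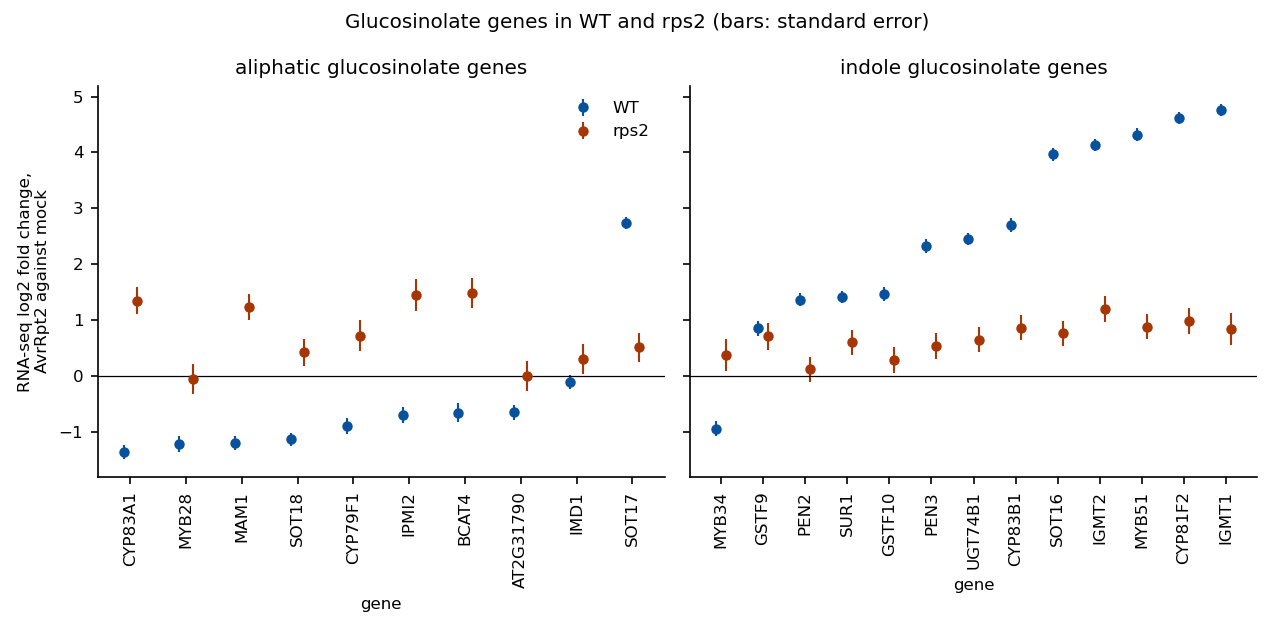
Log2 change in RNA-seq ± SE of aliphatic and indole glucosinolate genes after AvrRpt2 in WT (n = 3 per group) and rps2 (n = 2 per group). CYP83A1, MAM1, BCAT4 and IPMI2 lie below 0 in WT and above 0 in rps2, whereas most indole genes lie above 0 in both and further from 0 in WT.

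By list, the RNA-seq response was larger in WT for 7 of 7 camalexin genes (median difference 2.35, adjusted p = 2.05e-13, and adjusted p = 0.0349 with an estimated correlation). It was larger for 12 of 14 indole glucosinolate genes and smaller for 1 (median 1.82; MYB51 3.44 ± 0.19, adjusted p = 2.93e-14). It was larger for 11 of 18 salicylic acid genes and smaller for 1 (14 and 2 adjusted over the list alone, median 1.78, adjusted p = 2.05e-13). Both lists had an adjusted p = 0.106 with an estimated correlation. Phenylpropanoid genes responded more in 13 of 17 cases (13 and 1 less adjusted over the list alone; PAL2 3.29 ± 0.18, adjusted p = 1.56e-11). Cell-surface receptors and MAP kinases did so in 12 of 20 cases (13 adjusted over the list alone, adjusted p = 7.84e-11). For both there was an adjusted p = 0.178 with an estimated correlation. Aromatic amino acid genes responded more in 15 of 31 cases and less in 2 (17 and 3 adjusted over the list alone, adjusted p = 6.29e-10, and adjusted p = 0.191 with an estimated correlation). WRKY factors responded more in 10 of 17 cases (WRKY33 2.61 ± 0.20, adjusted p = 8.04e-08, and adjusted p = 0.199 with an estimated correlation). Aliphatic glucosinolate genes responded less in 7 of 10 cases and more in 1, SOT17 (8 and 1 adjusted over the list alone, median -1.59, adjusted p = 0.000144, and adjusted p = 0.178 with an estimated correlation). Jasmonate response genes split, 3 more and 7 less in WT of 16 (5 and 7 adjusted over the list alone, adjusted p = 0.906), with TAT3 at 3.58 ± 0.39 and ORA59 at -2.12 ± 0.23.

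Larger responses in WT were also called for the cell death (5 of 8 larger, adjusted p = 0.00247) and ethylene lists (5 larger and 1 smaller of 11, adjusted p = 0.000978). The same held for the jasmonate synthesis (6 larger and 1 smaller of 13, 7 and 2 adjusted over the list alone, adjusted p = 0.000528), chaperone (4 of 6 larger, adjusted p = 0.000452) and intracellular receptor lists (3 of 16 larger, 8 with median-centred libraries or quantile scaling and 7 under voom, adjusted p = 0.00495). These 5 lists had an adjusted p = 0.178 to 0.563 with an estimated correlation. N-hydroxypipecolic acid genes were called at adjusted p = 0.0317 (FMO1 1.91 ± 0.22), lost with median-centred libraries, with an adjusted p = 0.34 with an estimated correlation. Light harvesting (median -0.09) and carbon fixation genes (median -0.07) did not differ by the test (adjusted p = 0.78 each). Sphingolipid genes had a median of -0.04, a mean of 0.15 and no call (adjusted p = 0.297), and in Ribo-seq a median of -0.12, a mean of 0.15 and no call (adjusted p = 0.435). limma called 3097 of 14841 genes, 1619 with a WT minus rps2 difference above 0 (larger) and 1478 below 0 (smaller). The latter include genes that fell further in WT. Voom called 5176, 1802 larger and 3374 smaller, and quantile scaling 1962 and 2421. Without rps2 mock RNA-seq replicate 1 there were 1499 larger and 2890 smaller. The smaller ones numbered 814 without rps2 mock RNA-seq replicate 2, 718 without rps2 AvrRpt2 RNA-seq replicate 2, and 877 and 936 without WT mock RNA-seq replicate 1 and 3. WT and rps2 libraries stand in separate tables with no shared library, so background and batch cannot be told apart in these differences.

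Of 207 genes that rose in rps2 RNA-seq and were tested in WT, 160 also rose in WT, against 43.2 by chance. Of 150 that fell 137 also fell in WT, against 54.1 by chance. These counts were 321 and 141 without rps2 mock RNA-seq replicate 1, 40 and 44 without rps2 mock RNA-seq replicate 2, 62 and 35 without rps2 AvrRpt2 RNA-seq replicate 1, 112 and 202 without rps2 AvrRpt2 RNA-seq replicate 2, and at most 8 with quantile scaling, median-centred libraries or no filter. Across genes the slope of the rps2 on the WT change was 0.19. In opposite directions were 27 genes, 25 of them down in WT and up in rps2, among them CYP83A1, MAM1 and DREB26. There were 95 without rps2 mock RNA-seq replicate 1, 9 without rps2 mock RNA-seq replicate 2, 14 without rps2 AvrRpt2 RNA-seq replicate 2, and at most 1 with quantile scaling, median-centred libraries or no filter. In Ribo-seq 45 rose in both backgrounds, against 9.6 by chance, 23 fell in both, against 6.5, and 4 were opposite, or 16 under voom and 10 without rps2 AvrRpt2 Ribo-seq replicate 1. Under voom 173 rose in both, against 36.6, and 178 fell in both, against 83.3; without rps2 AvrRpt2 Ribo-seq replicate 1 it was 23, against 6, and 71, against 34.2. Those rising in both were 21 without rps2 mock Ribo-seq replicate 1, 3 without rps2 mock Ribo-seq replicate 2 and 23 without rps2 AvrRpt2 Ribo-seq replicate 2, and at most 1 gene fell in both in these fits. The 4 were DREB26 (-1.47 in WT and 0.93 in rps2), CAMBP25, a calmodulin-binding protein (0.54 and -0.93), AT3G57062 (-0.56 and 1.17) and AT4G08555 (1.74 and -0.99). All of them but DREB26 were chosen after their values were seen. None of the 4 was still opposite without rps2 mock Ribo-seq replicate 1 or 2 or with no filter, only AT3G57062 was without rps2 AvrRpt2 Ribo-seq replicate 2, and DREB26 was not without rps2 AvrRpt2 Ribo-seq replicate 1 nor AT3G57062 without WT AvrRpt2 Ribo-seq replicate 2. With quantile scaling DREB26 and AT4G08555 were, with median-centred libraries AT4G08555, and under voom DREB26 and CAMBP25.

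The same difference in Ribo-seq gave larger WT responses for PBS3 (4.91 ± 0.26), ABCG40 (4.55 ± 0.28), CYP79B2 (4.43 ± 0.25), ICS1 (4.31 ± 0.26), CCR2 (4.06 ± 0.27) and PAD3 (3.95 ± 0.29). The difference was below 0 for DREB26 (-2.40 ± 0.25), AGP17 (-1.95 ± 0.25) and BES1, a brassinosteroid regulator (-1.37). AGP17, at -2.73 in WT, fell further there than in rps2. Camalexin genes responded more in 7 of 7 cases (median 1.98, adjusted p = 3.15e-17, and adjusted p = 0.0365 with an estimated correlation). Indole glucosinolate genes did so in 12 of 13 cases (median 2.01, adjusted p = 1.8e-22, and adjusted p = 0.0774 with an estimated correlation), and salicylic acid genes in 10 of 15 (11 adjusted over the list alone, adjusted p = 4.27e-17, and adjusted p = 0.107 with an estimated correlation). Aromatic amino acid genes responded more in 11 of 28 cases (12 more and 1 less adjusted over the list alone; ASA1 1.96 ± 0.25, adjusted p = 2.37e-06, and adjusted p = 0.467 with an estimated correlation). Phenylpropanoid genes responded more in 7 of 17 cases (8 adjusted over the list alone, adjusted p = 5.26e-09, and adjusted p = 0.316 with an estimated correlation). Cell-surface receptors (10 of 19, and 6 without WT AvrRpt2 Ribo-seq replicate 1 or rps2 mock Ribo-seq replicate 1; 12 adjusted over the list alone, adjusted p = 6.78e-10) and WRKY factors (6 of 15, 8 adjusted over the list alone, adjusted p = 6.68e-08) were called larger in WT, both with an adjusted p = 0.318 with an estimated correlation. Cell death (3 of 7, 4 adjusted over the list alone, adjusted p = 0.000349) and ethylene genes (5 more and 1 less of 10, adjusted p = 0.00225) were called too, with an adjusted p = 0.316 and 0.385 with an estimated correlation. Light harvesting (1 of 36 less, 14 with quantile scaling and 12 under voom, median -0.36) and carbon fixation genes (1 of 18 less, 3 adjusted over the list alone, 6 with median-centred libraries, 13 with quantile scaling and 11 under voom, median -0.50) were called lower in WT at adjusted p = 0.00162, with an adjusted p = 0.66 and 0.572 with an estimated correlation. The aliphatic glucosinolate list was not called (adjusted p = 0.266). CYP83A1 (-1.08 ± 0.27) and MAM1 (-1.01 ± 0.28) passed the test but lost their calls without rps2 AvrRpt2 Ribo-seq replicate 1. CYP83A1 was then at -0.73 and MAM1 at -0.57, and the call of MAM1 also ended without rps2 mock Ribo-seq replicate 2, at -0.98.

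limma called 1309 of 11211 genes for this difference in Ribo-seq, 935 above 0 (larger) and 374 below 0 (smaller). The latter include genes that fell further in WT. Voom, which shifted the median of all genes by -0.13, called 1154 larger and 2043 smaller, median-centred libraries gave 1297 and 799 and quantile scaling 1183 and 1015. The smaller ones numbered 157 without rps2 mock Ribo-seq replicate 2, 236 without WT mock Ribo-seq replicate 1 and 249 without WT AvrRpt2 Ribo-seq replicate 3.

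Translational efficiency responses differed between WT and rps2 for 6 of 11208 genes by limma, all lower in WT, with 528 genes at unadjusted p under 0.05 where 560 would be by chance. They were PXMT1 (-1.50, adjusted p = 0.0268), the peroxidase PRXCA (-1.45), ORS1 (-2.24), AT1G30190 (-1.77, adjusted p = 0.0194), AT2G44578 (-1.90) and AT2G23270 (-2.24), the last 3 outside the rule for named genes and chosen after their values were seen. Apart from ORS1, which was not examined for this, their mean RNA-seq levels were 15.35 to 36.97 RPKM in WT AvrRpt2. In the other RNA-seq groups they were 1.061 RPKM or below, where a pseudocount of 1 weighs heavily on the ratio. Voom, a pseudocount of 0.1 and median-centred libraries each called 0 (569, 351 and 1004 unadjusted). limma also called 0 without WT mock RNA-seq replicate 1 or 2, WT mock Ribo-seq replicate 3 or rps2 mock Ribo-seq replicate 1 or 2. It called 1 without rps2 AvrRpt2 RNA-seq replicate 2 and 3 without WT mock RNA-seq replicate 3, WT mock Ribo-seq replicate 2, WT AvrRpt2 Ribo-seq replicate 3, rps2 mock RNA-seq replicate 2 or rps2 AvrRpt2 Ribo-seq replicate 2. It called 30 without rps2 mock RNA-seq replicate 1, 31 without rps2 AvrRpt2 RNA-seq replicate 1 and 42 without rps2 AvrRpt2 Ribo-seq replicate 1. The RNA-seq responses enter this difference with a minus sign too, so its list calls were not separated from spread in RNA-seq. Aliphatic glucosinolate genes were called higher in WT as a list (4 of 5 adjusted over the list alone, median 1.42, adjusted p = 1.64e-06, and adjusted p = 0.215 with an estimated correlation). So were phloem (0.40, adjusted p = 0.00304, and adjusted p = 0.66 with an estimated correlation) and folding genes (0.22, adjusted p = 0.0212, and adjusted p = 0.778 with an estimated correlation). Salicylic acid (median -0.45, adjusted p = 0.00304), camalexin (-0.36, adjusted p = 0.00474) and aromatic amino acid genes (-0.33, adjusted p = 0.000107) were called lower in WT. So were phenylpropanoid (-0.32, adjusted p = 6.47e-05) and jasmonate synthesis genes (-0.25, adjusted p = 0.00474), all 5 with an adjusted p = 0.66 with an estimated correlation. Under voom the medians of the salicylic acid and camalexin lists were -0.19 and -0.01. Carbon fixation (-0.51), ribosomal protein (-0.26) and light harvesting genes (-0.21) were called lower as well, with an adjusted p = 0.73 to 0.809 with an estimated correlation. Without rps2 AvrRpt2 Ribo-seq replicate 1, 7 lists were called. Indole glucosinolate genes (median 0.01, mean -0.13) and intracellular receptors (median 0.06, mean -0.04) were not called. The test found 0 of 100 simulated genes with a 2-fold difference in efficiency and 67 of 100 with a 4-fold difference, while voom found 40 and 88. Unchanged genes called numbered 6 by the test and 20 by voom.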

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

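Except for the interaction tests of WT minus rps2, the pseudocount test of translational efficiency and the splits of the samples, the tests in this part were chosen after the result was seen. Background and batch cannot be told apart in any difference between WT and rps2.

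The responses of WT and rps2 differed, by the interaction test, for 3097 genes and 14 lists in RNA-seq, for 1309 genes and 11 lists in Ribo-seq and for 6 genes and 11 lists in translational efficiency. With an estimated correlation the lists called were 1, 1 and 0. The efficiency genes called were 0 under voom, with a pseudocount of 0.1 or with median-centred libraries. Genes called in opposite directions in WT and rps2, with a called difference, numbered 27 in RNA-seq and 4 in Ribo-seq. The 27 were at most 1 with quantile scaling, median-centred libraries or no filter, 95 without rps2 mock RNA-seq replicate 1, 9 without rps2 mock replicate 2 and 14 without rps2 AvrRpt2 replicate 2. None of the 4 was opposite without rps2 mock Ribo-seq replicate 1 or 2. DREB26 differed by -2.75 in RNA-seq and by -2.40 in Ribo-seq. Among aliphatic glucosinolate genes, CYP83A1 differed by -2.71, MAM1 by -2.43, IPMI2 by -2.14 and BCAT4 by -2.13 in RNA-seq. In translational efficiency ORS1 differed by -2.24, PXMT1 by -1.50 and PRXCA by -1.45. Mean RNA-seq levels of PXMT1 and PRXCA were 1.061 RPKM or below in every group but WT AvrRpt2.

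In WT, efficiency estimates tended to run against the RNA-seq change, with 160 genes called lower and 42 higher (202 in all). Simulations without any change in efficiency gave a median of 180 calls (151 to 202) with a pseudocount of 1, against at most 3 with 0.1, and 95 to 113 of the genes called in the data were called there too, consistent with the pseudocount shrinking the sparser Ribo-seq values more. Under voom, efficiency still ran against the RNA-seq change with a Spearman rho of -0.15, beyond the -0.12 to -0.09 of the simulations. The RNA-seq change enters efficiency with a minus sign, so its spread alone makes rho negative. The simulations drew each gene on its own and left out spread shared by the genes of a library. In rps2, rho under voom was -0.49 with 0 genes called. This test thus cannot decide whether a change that does not come from the pseudocount remains. A biological change in ribosome loading thus stays open for the set of genes, and no single gene was called under voom.

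Clock-related genes (GI, CDF1, CDF3, AT1G69570 and CCA1) were among the falls in rps2 RNA-seq. The median over the 8 genes called lower, -1.23, was never nearer 0 than -1 in the 4 fits that each leave out 1 library. These genes were chosen because they were called lower with all libraries. Of the 369 genes called in rps2 RNA-seq, 366 had groups that did not overlap. Leaving out 1 library could thus hardly turn their sign, so this test cannot decide whether 1 library was the source. A different collection time of mock and AvrRpt2 leaves could not be decided. Morning genes not among those first seen were at a median of -0.76 and genes of an evening and photoperiod list at -0.05, a difference of -0.71. The latter list mixes evening clock genes with photoperiod genes such as CDF2 (-0.43), so its median does not stand for evening genes only. That morning set holds CCA1 (-1.27), named above among the falls, so it is not independent of the pattern. In WT, moreover, the medians of the morning and of the evening and photoperiod genes were -0.90 and -0.09. An earlier form of this test, on the evening and photoperiod genes alone, gave a median near 0 that decides nothing. An effect of the bacteria on clock genes in both backgrounds, and a shared difference in collection time, both stay possible, and the labels give no clock times.

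Genes most induced in WT were often somewhat higher in rps2 after AvrRpt2. RNA of WT plants in the rps2 AvrRpt2 samples would raise them all by a common share of their WT rise. Of the 100 genes that rose most, 43 had a share within a factor of 2 of the median share (33 to 49 with each rps2 library left out), against 75 to 87 in 20 simulated admixtures. The shares that single genes would need ran from -2.2% to 26%, with ICS1 at -0.6%, AACT1 at 13.1% and WRKY75 at 26%, which argues against admixture as the whole source. A response of rps2 plants to other signals of the bacteria may account for it and was not tested.

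For the WT counts, the 10 splits of 3 against 3 libraries are too few for a share under 0.05. For efficiency, RNA-seq and Ribo-seq libraries with equal replicate numbers were kept together, a pairing that the labels do not state. The real split gave 8394 genes in RNA-seq, 4785 in Ribo-seq and 202 in translational efficiency. The highest of the other splits gave 0 in each, so that 1 of 10 splits was as large. The other splits mix mock and AvrRpt2 libraries in both groups, which puts the treatment effect into their spread, so their 0 calls decide nothing.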

How the results depend on the processing

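Voom, rescaled Ribo-seq values, the paired settings, the left-out libraries for lists and the counts of shared and opposite genes under alternatives were chosen after seeing the data. Of 18063 values of named genes under an alternative (1086 pairs of gene and comparison), 17172 kept their direction and their side of the threshold, 659 lost and 218 gained a call, and 14 turned. Named genes kept their calls in every setting in 103 of 107 cases in WT RNA-seq, 85 of 95 in WT Ribo-seq, 72 of 83 for the RNA-seq and 55 of 69 for the Ribo-seq difference, but in 0 of 23 for WT efficiency, 1 of 41 in rps2 RNA-seq (ORA59), 0 of 21 in rps2 Ribo-seq and 0 of 3 for the efficiency difference. In rps2, with 2 libraries per group, 64 of 100 simulated genes with a 2-fold change were found by RNA-seq and 46 by Ribo-seq. Depth and number of libraries were not tested apart. Unchanged genes called in these simulations numbered 35 and 17, against 27 and 19 in WT. Spread shared by the genes of a library was not simulated.

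WT efficiency calls were 0 with a pseudocount of 0.1, 313 with no filter, 352 with the lysate block, 0 under voom, 0 with rescaled Ribo-seq values, 18 with a pseudocount of 0.1 and the lysate block, and 9 with a pseudocount of 0.25 and median centring; the first and the rescaled setting act on the pseudocount by construction. Calls in rps2 RNA-seq were 2 with no filter, 14 with quantile scaling, 16 with median centring, 219 with the replicate block and 223 with one fit over both assays. The prior degrees of freedom of limma were 55.2 as deposited but 4.62, 5.07 and 5.25 in the first 3 of these; no fit changed the prior alone. In rps2 Ribo-seq they were 0 with no filter (6.42 against unlimited), 46 with median centring, 322 with the block, 56 with one fit and 417 under voom; rps2 efficiency gave 11 with number within assay as a block. The RNA-seq difference gave 5176 under voom, and the Ribo-seq difference 2198 with quantile scaling, 2096 with median centring and 3197 under voom. The efficiency difference gave 33 with no filter, 3 with quantile scaling, and 0 with a pseudocount of 0.1, median centring, voom, rescaled values and both paired settings. Apart from the pseudocount, the cause was not tested. Deviations of RNA-seq and Ribo-seq libraries with the same number correlated at 0.05 to 0.37 in WT mock (own number best in 3 of 3), 0.06 to 0.21 in WT AvrRpt2 (2 of 3), 0.22 in rps2 mock and -0.06 in rps2 AvrRpt2. Whether the numbers mark a shared lysate stays open, and the counts with a block stand only as alternatives.

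With an estimated correlation, lists called by camera numbered 0, 0 and 0 in rps2 (RNA-seq, Ribo-seq, efficiency), 0, 1 and 0 in WT, and 1, 1 and 0 for the differences, against 2, 0 and 2, then 4, 3 and 2, and 6, 3 and 1 at an unadjusted p under 0.05. Leaving out 1 library gave 7300 to 8384 genes in WT RNA-seq, 3765 to 5407 in WT Ribo-seq, 111 to 287 for WT efficiency, 99 to 778, 3 to 195 and 0 to 59 in rps2, and 2203 to 4389, 1052 to 1675 and 0 to 42 for the differences. Lists called ranged over 17 to 19, 13 to 18 and 5 to 11 in WT, 12 to 15, 6 to 13 and 7 to 11 in rps2, and 13 to 15, 11 to 15 and 7 to 11 for the differences.

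Turned values were AT5G60390 in WT Ribo-seq at -0.29 with quantile scaling, and in WT efficiency IGMT1 at 0.50 (pseudocount 0.1, with and without the lysate block), 0.75 (voom), 0.54 (rescaled) and 0.14 (pseudocount 0.25, median centring), GSTU12 at 0.34 (voom) and 0.13 (rescaled), CYP71A12 at 0.19 (voom) and 0.26 (rescaled), LCR67 at 0.02 and WRKY75 at 0.10 (voom), and NHL25 at 0.12 and PP2-B14 at 0.01 (rescaled).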

Other observations

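The gene families in this part were chosen after the data were seen, by shared symbol, and tested with camera over 88 families in WT RNA-seq, 64 in WT Ribo-seq, 87 in rps2 RNA-seq and 90 for the RNA-seq difference. Calcium-dependent protein kinases (CPK), which relay calcium signals, rose in 10 of 14 cases in WT RNA-seq with none falling (median log2 change 1.02; CPK29 1.81, CPK4 1.54; adjusted p = 0.000129). Cysteine-rich receptor-like kinases (CRK) rose in 16 of 26 cases and fell in 6 (CRK39 3.81, CRK36 3.24; adjusted p = 0.000444). Tau-class glutathione transferases (GSTU), which conjugate reactive compounds, rose in 13 of 18 cases and fell in 4 (GSTU12 4.06, GSTU11 3.68; adjusted p = 0.000495). Exocyst genes, which tether secretory vesicles, rose in 10 of 15 cases and fell in 2 (EXO70H4 2.37, EXO70B2 1.84; adjusted p = 0.000444), and NAC transcription factors in 21 of 29 with 3 falling (median 0.44; adjusted p = 0.000444). Chloroplast photosystem assembly genes named HCF fell in 12 of 12 cases (median -0.62; adjusted p = 0.00352), and 3-ketoacyl-CoA synthases (KCS), which elongate fatty acids for wax and suberin, in 10 of 11 (median -0.50; adjusted p = 0.0116). B-box factors (BBX), many of them light regulators, fell in 10 of 12 cases and rose in 2 (BBX15 -1.18, BBX14 -1.14; adjusted p = 0.0327). Serine carboxypeptidase-like genes (SCPL) fell in 13 of 16 cases (adjusted p = 0.0317) and plastid transcription complex genes (PTAC) in 11 of 13 (adjusted p = 0.0329). Each of these WT RNA-seq calls had an adjusted p = 0.974 with an estimated correlation.

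In WT Ribo-seq, GSTU genes rose in 11 of 15 cases and fell in 3 (adjusted p = 6.91e-05) and CPK genes rose in 10 of 13 (adjusted p = 0.00269), both with an adjusted p = 0.992 with an estimated correlation. The RNA-seq response was larger in WT than in rps2 for 9 of 15 CPK and 8 of 15 exocyst genes with none smaller (adjusted p = 0.000921 each, and adjusted p = 0.988 with an estimated correlation). In rps2 RNA-seq, arabinogalactan protein genes (AGP), of the cell wall and plasma membrane, were called lower as a family, with 4 of 22 falling and 1 rising (median -0.27; adjusted p = 0.000175, and adjusted p = 0.993 with an estimated correlation).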
